A study of Mus musculus with 24 samples.

How the data were processed

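RNA was measured in 24 libraries of mouse conventional dendritic cells of type I (cDC1s). Per the labels, bone marrow was cultured for 17 days with GM-CSF and FLT3L, and the cDC1s were sorted by flow cytometry. The marrow came from STAT3-floxed mice without the CD11c-Cre transgene, called WT here, or with it, called KO here. CD11c-Cre removes floxed DNA in cells with CD11c promoter activity, among them dendritic cells. The sorted cells received PBS, IL-10 at 10 ng/mL, poly I:C at 20 µg/mL, or IL-10 plus poly I:C for 6 h. That gives 8 groups of 3 libraries. The sample titles number 3 cultures per genotype, and each number recurs under the 4 treatments, so libraries are named here by culture and treatment (WT1 PBS). The labels do not state that the cultures came from separate animals, so p-values measure the spread between these samples.

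Per the labels' protocols, total RNA was isolated with Qiagen RNeasy kits and libraries were made with an Illumina TruSeq RNA kit. Per the submitters' processing notes, base calling used CASAVA 1.8.2, reads were aligned to GRCm38 (mm10) with TopHat2 2.1.1, and genes were quantified with RSEM 1.2.31. The deposited values are RSEM expected counts per gene, and no scaling of these expected counts by the authors is recorded in the sources used here. The annotation release is not given in the sources used here: 99.48 % of the gene identifiers occur in GENCODE M21, and 88.2 % carry the same version there. Gene symbols are those of the deposited table, and coordinates are from GENCODE M21 on GRCm38, numbered from 1. The sources used here do not say whether the counting used the strand of reads, so reads of overlapping or antisense genes cannot be told apart. Genes with near-identical copies are uncertain because expected counts divide shared reads between copies. Among the genes named, these are members of the class I H2, Gbp and Iigp families.

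Expected counts were rounded to whole numbers. Of 49585 genes in the table, 26841 had no count in any library. The filterByExpr function of edgeR (minimum count 10, minimum total 15, on the 8 groups) kept 13445 genes, which hold 99.96 % of all counts. The other 36140 genes were not tested. No library was left out, and no column lacked a matching sample. In the table, 93 symbols occur more than once and were kept apart by identifier. Library totals were 15.7 to 24.9 M counts. A gene with no count in a group was given a floor of 3 counts over that group, which is the upper limit that a count of 0 allows, and folds against it are written "at least". Floors cover counting error only. Values are given as CPM, counts scaled to a common total with edgeR's TMM factors, as mean ± SD of 3 libraries.

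The fit was edgeR 4.0.16 in R 4.3.3: TMM scaling, the robust quasi-likelihood test on 8 group means over all 24 libraries, two-sided, with Benjamini-Hochberg adjustment over the tested genes at 0.05. Every adjusted p for a gene is from this test unless another is named. There were 13 comparisons: 6 of a treatment with its control within a genotype, 4 of KO with WT within a treatment, and 3 tests of whether a treatment effect differed between the genotypes (KO effect minus WT effect). "Rose", "fell" and "changed" are used only of genes past this threshold. The design, the gene lists, the naming rule and the alternatives (except those said to be chosen after seeing the data) were fixed before the data were examined. The rule names Stat3; in each comparison the 6 rising and the 6 falling genes with the largest log2 fold change among those past the threshold, with at least 8 CPM on average over all libraries and the same direction in all 3 same-numbered pairs (no pairs for the 3 tests between genotypes), passing over predicted genes; up to 4 members with the smallest p of each list described; and 14 fixed genes (Socs3, Il10, Ifnb1, Cxcl9, Cxcl10, Isg15, Ifit1, Irf7, Il12b, Il6, Tnf, Cd40, Cd274 and 1 that is not reported here). Genes named by the rule whose call was lost without a single library are given with the adjusted p or the number of genes called without it, or are left out.

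There were 21 gene lists, with measured members where fewer than listed: interferon-stimulated genes (40), interferon-gamma-associated genes (20), interferon genes (2 of 12), STAT3 target genes (20), inflammatory cytokines and chemokines (22 of 24), NF-kB target genes (18), dendritic cell maturation (20), MHC class I presentation (20), MHC class II presentation (14 of 15), cDC1 identity (20), cell cycle (20), glycolysis (16), cholesterol synthesis (19), stress and handling (16), and markers of cDC2s (7 of 10), pDCs (6 of 10), monocytes and macrophages (12 of 15), neutrophils (3 of 12), mast cells and basophils (3 of 10), lymphocytes (3 of 12) and erythroid cells (2 of 9). Each list has 3 results: its members past the threshold over all genes, its members past the threshold with p-values adjusted over the list alone, and camera in limma 3.58.1. Camera tests whether a list's genes move relative to the other genes. It was run two-sided with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. It was not run for the interferon genes and the erythroid markers, with 2 measured members each.

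Same-numbered libraries were checked for pairing. Across genes, which are not independent replicates, their deviations from the group means correlated by 0.13 to 0.77 in all 18 pairs of the 6 treatment comparisons. Those of differently numbered libraries correlated by -0.63 to 0.2. The numbers therefore pair libraries within a genotype, and the fit with the culture as a block is given for many results whose call or count it changed. The alternatives tried were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, no low-count filter, only the groups compared, the replicate block, each library left out in turn, and camera with the block. Scaling to total counts only and leaving out all 4 libraries of a culture were chosen after seeing the data. The fits were tested on simulated data with 200 changed genes among 13445. For the comparison of IL-10 with PBS in KO, 72 of 100 genes changed by 2-fold and 97 of 100 changed by 4-fold were called. For the genotype difference in the response to IL-10 added to poly I:C, the counts were 19 and 88 of 100. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.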

Results

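Gene expression was measured in cDC1s, the dendritic cells specialised in presenting antigen to CD8 T cells. Per the series title, the study concerns STAT3 and the interferon that these cells make and respond to. STAT3 is the transcription factor through which IL-10, an anti-inflammatory cytokine, signals. Poly I:C is a synthetic double-stranded RNA that mimics viral RNA and is sensed by TLR3. The 24 libraries fall into 8 groups of 3: WT and KO cells given PBS, IL-10, poly I:C, or IL-10 plus poly I:C. Library totals were 19.2 to 21.5 M counts in WT with PBS, 18.5 to 21.6 in WT with IL-10, 15.7 to 24.9 in WT with poly I:C and 18.4 to 21.2 in WT with both. In KO they were 18 to 19.5 M with PBS, 19.5 to 23.5 with IL-10, 16.9 to 21.1 with poly I:C and 17.7 to 24.7 with both. The first principal component held 70.2 % of the variance and parted the libraries with poly I:C (65.9 to 121) from those without it (-119 to -53.7). Among WT libraries without poly I:C, WT3 PBS (-70.8) and WT3 IL-10 (-53.7) stood apart from the others, which lay at -119, -107, -103 and -96.3. TMM factors were 0.63 to 0.875 with poly I:C and 1.17 to 1.49 without it. Scaling to total counts only, chosen after seeing the data, moved the median log2 fold change of all genes by -1.03 in WT and -1.07 in KO for poly I:C against PBS. It moved it by 0.28 for IL-10 added to poly I:C in WT, by -0.28 for KO against WT under both, by -0.25 for the genotype difference in that response, and by -0.1 for IL-10 alone in WT. Fold changes below are relative to TMM scaling.

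**Figure D1:**
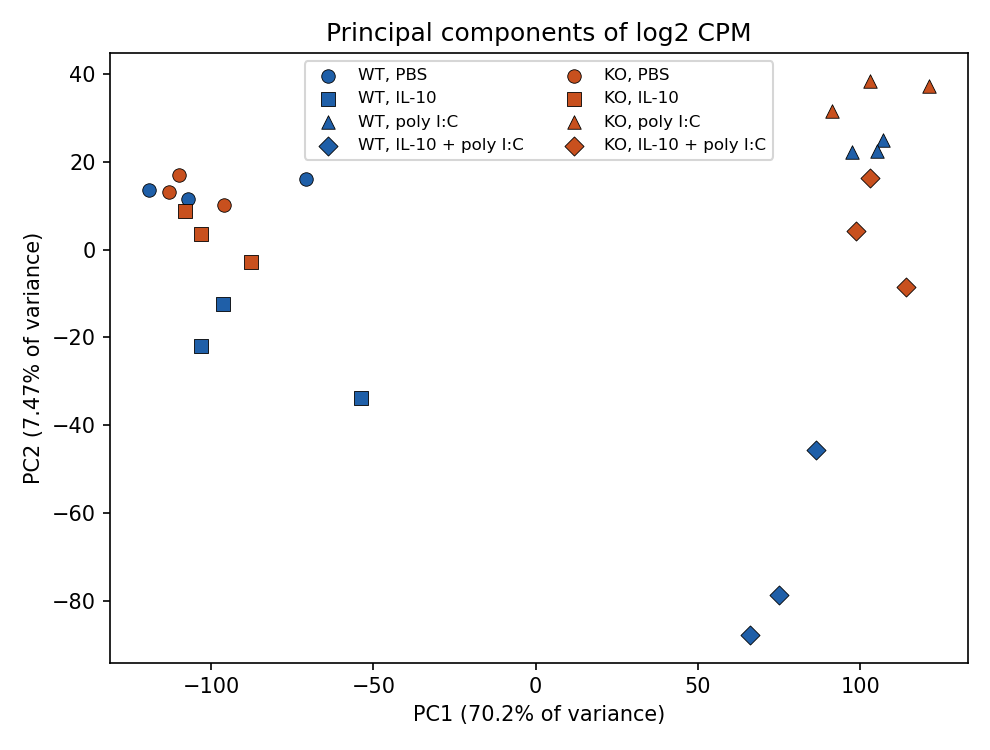
First principal component (70.2 % of variance) against the second (7.47 %) of the 24 libraries, coloured and marked by group. The 3 WT libraries with both stimuli lie lowest on the second, at -45.7, -78.8 and -87.8.

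Stat3 (ENSMUSG00000004040.16, GRCm38 chromosome 11, 100885098 to 100939540, minus strand), the targeted gene, was lower in every KO library than in any WT library of the same treatment. In the WT libraries, in the order of cultures WT1, WT2 and WT3, it stood at 370, 305 and 542 CPM with PBS, 586, 446 and 1030 with IL-10, 1610, 1020 and 1930 with poly I:C, and 2460, 1540 and 2760 with both. In KO1, KO2 and KO3 it stood at 166, 220 and 192 CPM with PBS, 206, 328 and 269 with IL-10, 622, 856 and 744 with poly I:C, and 855, 1220 and 1120 with both. The KO mean was 47.5 % of the WT mean with PBS, 39 % with IL-10, 48.8 % with poly I:C and 47.3 % with both. Against WT, the log2 fold change was -1.07 with PBS (adjusted p = 1, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), -1.36 with IL-10 (adjusted p = 0.087) and -1.04 with poly I:C (adjusted p = 0.73). With both stimuli Stat3 passed the test (-1.08, adjusted p = 0.015), but not without WT1 (adjusted p = 0.056), WT3 (0.078) or KO1 (0.065). The counts cover the whole gene, and the labels do not say which exons are floxed, so transcripts that lack only those exons are still counted. Poly I:C raised Stat3 in WT from 406 ± 122 to 1520 ± 462 CPM (log2 fold change 1.90, SE 0.31, adjusted p = 1.4e-05) and in KO from 193 ± 26.9 to 741 ± 117 CPM (1.94, adjusted p = 1.1e-05). IL-10 alone left Stat3 short of the threshold in WT (0.76, adjusted p = 0.31), and so did IL-10 added to poly I:C (0.57, adjusted p = 0.18). With the culture as a block both were past it (0.72, adjusted p = 0.0038, and 0.58, adjusted p = 0.0033).

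**Figure D2:**
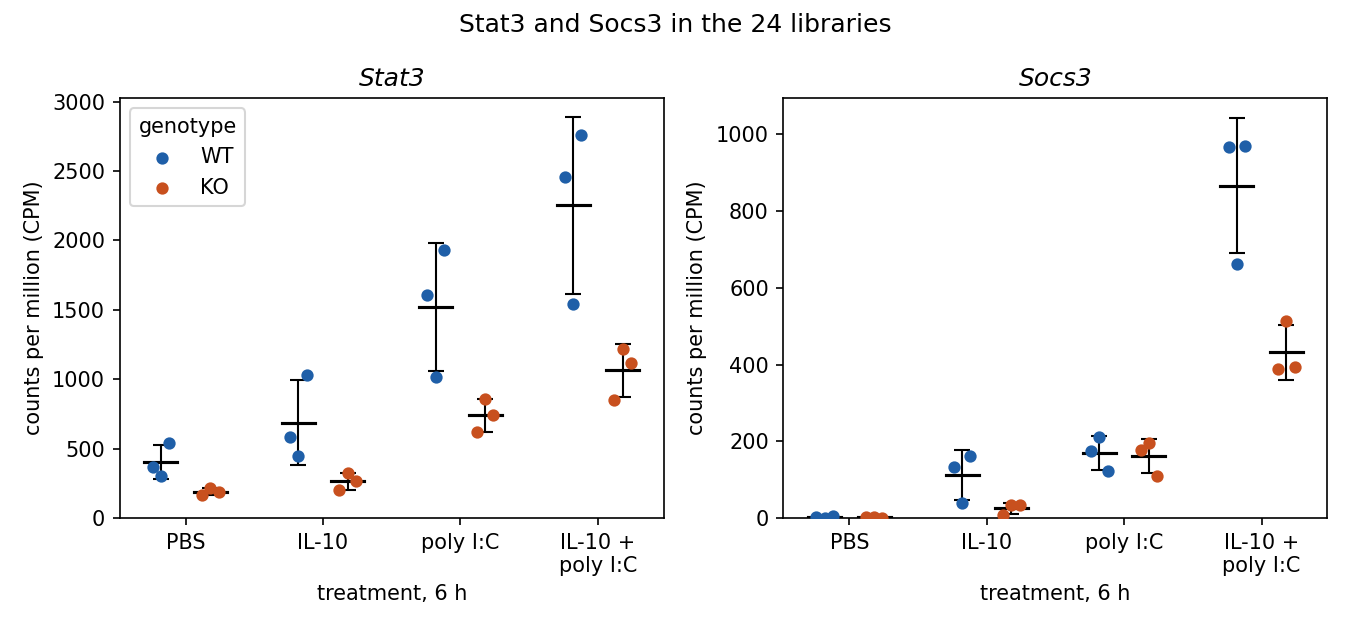
Stat3 and Socs3 in CPM per library against treatment for 6 h, WT in blue and KO in orange, with bars for mean ± SD of 3 libraries. Stat3 in KO lies below every WT library of the same treatment, and Socs3 with IL-10 reaches 111 CPM on average in WT and 25.7 CPM in KO.

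Poly I:C switched on cytokines and chemokines in WT cDC1s, the first question being what the viral mimic does alone. Il12b (ENSMUSG00000004296.14, chromosome 11, 44400063 to 44414033, plus strand), the subunit shared by IL-12 and IL-23, rose from 180 ± 130 to 10500 ± 1890 CPM (SD, n = 3, log2 fold change 5.86, SE 0.60, adjusted p = 6.7e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Il12a (ENSMUSG00000027776.12, chromosome 3, 68690644 to 68698547, plus strand), the other subunit of IL-12, had no count with PBS and 86.4 ± 20.4 CPM with poly I:C, at least 2470-fold more. Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007), an inflammatory cytokine, rose from 9.18 ± 7.9 to 1400 ± 121 CPM (log2 7.25, adjusted p = 3.6e-09), and Il6 from 1.17 ± 0.591 to 356 ± 23.7 CPM (log2 8.25, adjusted p = 3.4e-09). The chemokine gene Ccl3 rose from 0.32 to 325 ± 16.2 CPM (log2 10.02, SE 0.69, adjusted p = 1e-09). Lta, the gene of lymphotoxin alpha, had no count with PBS and 23.6 ± 8.74 CPM with poly I:C, at least 673-fold more. Il10 itself rose from 0.0259 to 1.62 ± 0.222 CPM (log2 5.76, adjusted p = 7.3e-05). Among the largest falls were those of Cxcr3, a chemokine receptor (22.2 ± 7.98 to 0.129 ± 0.152 CPM, log2 -7.18, adjusted p = 2e-08) and Zfp36l2, an RNA-binding protein that promotes mRNA decay (430 ± 104 to 5.69 ± 0.428 CPM, log2 -6.24, adjusted p = 3.7e-11). Others were Adgrg5 (-6.73), Vwa1 (-6.52) and the cyclooxygenase gene Ptgs1 (-6.26). Of 13445 genes, 8965 changed, 4084 up and 4881 down, and 6540 of them by 2-fold or more (2843 up, 3697 down). Higher calls were 45.6 % of the total with TMM and 17.6 % scaled to total counts only (1765 up, 8242 down).

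The interferon response rose as a whole with poly I:C in WT. All 40 interferon-stimulated genes rose (40 when adjusted over the list alone, median log2 fold change 3.27, camera adjusted p = 1.2e-13), a call not kept with an estimated correlation (adjusted p = 0.25 with an estimated correlation). Among them, Ifit1 rose from 41.6 to 1900 ± 26.8 CPM, Isg15, a ubiquitin-like modifier, from 83.4 to 1930 ± 649 CPM, and Irf7, the transcription factor that amplifies interferon production, from 301 to 2890 ± 29.2 CPM. The PBS libraries differed in this list: Isg15 stood at 15.4, 31.7 and 203 CPM in WT1, WT2 and WT3. Ifnb1 (ENSMUSG00000048806.4, chromosome 4, 88522025 to 88522774, minus strand), the gene of interferon beta, had no count with PBS and 5.58 ± 1.05 CPM with poly I:C, at least 159-fold more. Ifnl2, the other interferon gene measured, rose from 0.0129 to 0.887 CPM (adjusted p = 0.00019), so both measured interferon genes rose. Of the interferon-gamma-associated genes 19 of 20 rose (20 adjusted over the list alone, median 4.02, camera adjusted p = 6.3e-10, adjusted p = 0.2 with an estimated correlation). Among them were Cxcl9 (38.7 to 1870 ± 562 CPM) and Cxcl10 (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889, minus strand, 14.8 to 1130 ± 171 CPM), which attract T cells.

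Most inflammatory and maturation genes also rose in WT. Poly I:C raised 20 of 22 inflammatory cytokines and chemokines (20 adjusted over the list alone, median 5.36, camera adjusted p = 1.1e-08) and all 18 NF-kB target genes (18, median 2.71, 2.1e-10). It also raised 18 of 20 dendritic cell maturation genes (18, median 3.32, 3.8e-09) and 18 of 20 MHC class I presentation genes (18, median 1.74, 1.6e-08). With an estimated correlation these 4 calls were not kept (adjusted p = 0.2 for each with an estimated correlation). Nfkb1, a subunit of NF-kB, rose from 209 to 1430 CPM and the peptide transporter gene Tap1 from 389 to 1550 ± 28.4 CPM. The co-stimulatory genes Cd40 (75.1 to 2270 ± 63.5 CPM), Cd80 (5.93 to 101 ± 12.4 CPM) and Cd86 (180 to 895 ± 10.9 CPM) rose, as did Cd274, the gene of the inhibitory ligand PD-L1 (115 to 1430 ± 5.97 CPM). Of the STAT3 target genes 16 rose, 1 fell and 3 were not called (16 and 1 adjusted over the list alone, median 2.23, camera adjusted p = 1.4e-06, adjusted p = 0.2 with an estimated correlation). Socs3 (ENSMUSG00000053113.3, chromosome 11, 117966079 to 117970047, minus strand), a feedback inhibitor of cytokine signalling that STAT3 induces, rose from 3.71 ± 2.52 to 170 ± 44.1 CPM (log2 5.53, adjusted p = 1.6e-07). With the culture as a block and an estimated correlation, camera did pass the threshold for the interferon-gamma-associated, STAT3 target, NF-kB target, maturation and MHC class I lists (adjusted p = 0.02 each) and the inflammatory list (0.033).

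Metabolic, identity and cell cycle genes moved too. Glycolysis had 13 rises and 1 fall among 16 (the same adjusted over the list alone, median 0.92, camera adjusted p = 0.00024, adjusted p = 0.2 with an estimated correlation). Cholesterol synthesis had 13 rises and 2 falls among 19 (the same adjusted over the list alone, median 0.89, camera adjusted p = 0.0027, adjusted p = 0.49 with an estimated correlation). Scaled to total counts only, the medians of these lists were -0.11 and -0.12, with 3 rises and 4 falls, and 6 and 9. Stress and handling genes had 9 rises and 1 fall among 16 (the same adjusted over the list alone, median 1.27, camera adjusted p = 0.0027, adjusted p = 0.2 with an estimated correlation). Of the cDC1 identity genes 4 rose, 13 fell and 3 were not called (the same adjusted over the list alone, median -1.33, camera adjusted p = 0.014, adjusted p = 0.4 with an estimated correlation). Of the cell cycle genes 3 rose, 14 fell and 3 were not called (the same adjusted over the list alone, median -1.55, camera adjusted p = 0.0078, adjusted p = 0.2 with an estimated correlation). MHC class II presentation had 5 rises and 3 falls among 14 (the same adjusted over the list alone, camera adjusted p = 0.58), with a median of 0.29 and a mean of -0.07, but 1 rise and 9 falls (median -0.71) scaled to total counts only. In it March1, a ubiquitin ligase that removes MHC class II from the surface, fell from 50.8 ± 7.93 to 2.43 ± 0.113 CPM.

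Marker lists of other cells were small and none passed the camera test with poly I:C in WT. Counts below are the same adjusted over the list alone unless given. Of 12 monocyte and macrophage markers 2 rose and 6 fell (adjusted p = 0.54), among them Ccr2 (104 to 2.62 CPM), a chemokine receptor, and the lysozyme gene Lyz2 (1440 to 255 ± 29.9 CPM). Of 7 cDC2 markers 1 rose and 1 fell (median 0.14, mean -0.29, adjusted p = 0.64), of 6 pDC markers 2 rose and 2 fell (median 0.24, mean -0.38, 0.55), and the transcription factor gene Tcf4 was among the rises (26.3 to 138 CPM). Of 3 neutrophil markers 1 rose (adjusted p = 0.43). Of 3 mast cell and basophil markers 2 rose (adjusted over the list alone, 2 rose and 1 fell, 0.43), with Hdc, the enzyme that makes histamine, up from 0.552 to 10 CPM. Of 3 lymphocyte markers 1 rose (adjusted over the list alone, 0, median -0.21, mean 0.52, 0.87), and neither of 2 erythroid markers changed. Without some single libraries the changed members numbered 2 for neutrophil, 1 for mast cell and basophil and 0 for lymphocyte markers.

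In KO cDC1s poly I:C also raised the cytokine, interferon and maturation lists. Il12b rose from 178 ± 57.6 to 13000 ± 4170 CPM (SD, n = 3, log2 fold change 6.20, SE 0.61, adjusted p = 3.6e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Tnf rose from 8.48 to 1860 ± 570 CPM (log2 7.78), Il6 from 0.762 to 458 ± 268 CPM (9.21) and Ccl3 from 0.383 to 457 ± 271 CPM (10.19). Il12a had no count with PBS and 140 ± 73.9 CPM with poly I:C, at least 3750-fold more, and Ifnb1 had none with PBS and 10.7 ± 6.72 CPM with poly I:C, at least 288-fold more. Cxcl10 rose from 7.28 to 1330 ± 81.5 CPM (log2 7.51, adjusted p = 1e-05), Isg15 from 26 to 2000 ± 228 CPM (6.26, adjusted p = 8.6e-06), Ifit1 from 11.5 to 1960 CPM and Irf7 from 85.5 to 3010 CPM. Irf8, the transcription factor that specifies cDC1s, rose from 793 to 4310 ± 1270 CPM (2.44). Cxcr3 (18.2 to 0.0736 CPM), Ptger3, a prostaglandin E2 receptor gene (26 to 0.143 CPM), and Zfp36l2 (420 to 4.51 CPM, log2 -6.53, adjusted p = 2.1e-11) were among the largest falls. In all, 9074 genes changed, 4103 up and 4971 down, 6710 by 2-fold or more (2879 up, 3831 down). Higher calls were 45.2 % of the total with TMM and 17 % scaled to total counts only (1739 up, 8469 down).

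In KO all 40 interferon-stimulated genes rose (median 4.46, camera adjusted p = 7.4e-16, adjusted p = 0.21 with an estimated correlation). So did all 20 interferon-gamma-associated genes (median 5.14, 4.3e-10), both interferon genes and all 18 NF-kB target genes (median 2.73, 4.4e-10). Of the other lists, 18 of 22 inflammatory genes (median 5.36, 9.8e-09), 18 of 20 maturation genes (median 3.45, 1.5e-09) and 18 of 20 MHC class I genes (median 2.02, 3.4e-09) rose. Apart from that of the interferon-stimulated genes, these calls had adjusted p = 0.17 with an estimated correlation. Of the STAT3 target genes 16 rose and 1 fell (median 2.27, 6e-06, adjusted p = 0.17 with an estimated correlation), with Socs3 up from 2.38 to 161 CPM. Counts of these lists were the same adjusted over the list alone. Cd40 rose from 60.4 to 2440 CPM and Cd86 from 143 to 897 CPM. Of the cDC1 identity genes 4 rose and 13 fell (median -1.34, camera adjusted p = 0.028, adjusted p = 0.47 with an estimated correlation). Of the cell cycle genes 4 rose and 14 fell (median -1.44, 0.021, adjusted p = 0.23 with an estimated correlation). Glycolysis (13 rose, 1 fell, median 1.08, 5.9e-05), cholesterol synthesis (13 and 2, 0.79, 0.0027) and stress (8 and 2, 1.26, 0.0042) passed too, but not with an estimated correlation (adjusted p = 0.17, 0.49 and 0.17).

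Whether the poly I:C response differs between genotypes was tested directly, and no gene passed. By the test of the difference, 0 of 13445 genes were called by edgeR's quasi-likelihood test and 0 by DESeq2, with 350 at an unadjusted p under 0.05. Comparing KO with WT under poly I:C also gave 0 genes (604 at an unadjusted p under 0.05, DESeq2 7), and 1 gene without WT3 poly I:C or without KO3 poly I:C. The log2 fold changes of poly I:C in the genotypes, which share no library, correlated across 13445 genes by 0.90 (Pearson) and 0.94 (Spearman), where genes are not independent replicates. Of the 8965 genes changed in WT, 8927 (99.6 %) had the same sign in KO. In both genotypes 3701 genes rose, against 1250 for independent lists, and 4452 fell, against 1800. Il12b, Tnf, Cxcl10 and Ifnb1 were among the genes that did not pass in KO against WT under poly I:C. By camera the difference was above 0 for the interferon-stimulated genes (median 1, adjusted p = 1.1e-09), the interferon-gamma-associated genes (0.95, 0.0028) and MHC class I presentation (0.26, 0.011), with adjusted p = 0.96 for each with an estimated correlation. No member of these lists was called, over all genes or adjusted over the list alone. Without WT3 PBS, the library with the highest Isg15 among PBS samples, the first 2 medians were both -0.05.

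With PBS, edgeR's quasi-likelihood test called 0 genes between KO and WT (238 at an unadjusted p under 0.05, DESeq2 1). It missed even Stat3 (KO up to 220 CPM, WT from 305). The interferon-stimulated genes had a median log2 fold change of -1 in KO against WT (camera adjusted p = 2.3e-19) and the interferon-gamma-associated genes one of -0.92 (0.00019), with adjusted p = 0.65 for both with an estimated correlation. No member passed over all genes, and adjusted over the list alone 2 interferon-stimulated genes were lower. Mx1, an antiviral GTPase, stood at 80.4, 108 and 482 CPM in WT1, WT2 and WT3, and at 55.7, 96.2 and 162 CPM in KO1, KO2 and KO3. Without WT3 PBS these medians were 0.03 and 0.13. The cell cycle (-0.22, 0.0016) and cDC1 identity (-0.12, 0.012) were lower by camera too and cholesterol synthesis higher (0.12, 0.024), with adjusted p = 0.65, 0.65 and 0.88 with an estimated correlation. Under poly I:C the 3 neutrophil markers had a median of -4.9 in KO (camera adjusted p = 0.023, adjusted p = 0.19 with an estimated correlation), none called over all genes and 2 lower adjusted over the list alone.

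IL-10 alone, the second question, raised a small set of genes in WT cDC1s. Socs3 rose from 3.71 ± 2.52 to 111 ± 64.9 CPM (SD, n = 3, log2 fold change 4.92, SE 0.58, adjusted p = 0.00012, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Kif1a, a kinesin motor, rose from 1.68 ± 0.34 to 38 ± 23.8 CPM (log2 4.49, SE 0.52, adjusted p = 0.00012). Wfdc17, a secreted protein of myeloid cells, rose from 1.16 ± 0.614 to 32.5 ± 21.7 CPM (4.82, adjusted p = 0.0034) and Dram1, a lysosomal protein of autophagy, from 3.19 ± 1.12 to 45.5 ± 21.1 CPM (3.84, SE 0.38, adjusted p = 2.1e-05). The STAT3 targets Bcl3 (45.9 ± 20.5 to 177 ± 54.6 CPM, log2 1.95, adjusted p = 0.0015) and Sbno2 (136 ± 25.4 to 349 ± 145 CPM, 1.36, adjusted p = 0.0039) rose. So did the stress-response gene Ier3 (11.6 ± 6.68 to 70.8 ± 26.3 CPM, 2.61, adjusted p = 0.0015). The cyclooxygenase gene Ptgs2 rose from 0.326 to 3.68 ± 2.48 CPM and the guanylate-binding protein gene Gbp5 from 9.86 ± 7.68 to 89.4 ± 58.7 CPM (3.18, adjusted p = 0.0036). Of 13445 genes 148 changed, 143 up and 5 down, 116 by 2-fold or more (112 up, 4 down). With the culture as a block the number was 532 (424 up, 108 down), and with DESeq2 371 (311 up, 60 down). One of the 5 falls was Egr2, an early response transcription factor (7.2 ± 2.07 to 1.69 ± 0.785 CPM, log2 -2.09, SE 0.37, adjusted p = 0.0039). The others were Wnt9a (-2.02, adjusted p = 0.022) and Sulf2 (-1.41, adjusted p = 0.036), both named here after their values were seen, and Stx16 (-0.68, adjusted p = 0.032) and Ifnlr1 (-1.51, adjusted p = 0.04). Stx16 was not called without WT1 PBS (adjusted p = 0.1), WT2 PBS (0.11), WT3 PBS (0.098), WT1 IL-10 (0.099) or WT3 IL-10 (0.24), and Ifnlr1 not without WT1 PBS (0.11), WT3 PBS (0.15), WT1 IL-10 (0.15), WT2 IL-10 (0.096) or WT3 IL-10 (0.061). The number of changed genes was 71 without WT1 PBS, 79 without WT2 PBS, 230 without WT2 IL-10, 59 without WT3 IL-10, and 10 with only these groups in the fit, where Dram1 alone of the genes named here kept its call.

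The STAT3 target and glycolysis lists were higher with IL-10 in WT by camera. Of the STAT3 target genes 8 rose and 12 were not called (15 rose adjusted over the list alone, median 1.24, camera adjusted p = 1e-17, and adjusted p = 0.023 with an estimated correlation). Of the glycolysis genes 7 rose and 9 were not called (14 rose adjusted over the list alone, median 0.59, camera adjusted p = 3.2e-17, and adjusted p = 0.023 with an estimated correlation). They included Pfkl (33.1 ± 1.34 to 64.1 ± 9.32 CPM, log2 0.95, SE 0.17, adjusted p = 0.0034) and Tpi1 (55.6 ± 1.86 to 110 ± 14.5 CPM, 0.99, SE 0.17, adjusted p = 0.0035). The pyruvate kinase gene Pkm rose from 561 ± 62.5 to 1120 ± 248 CPM (log2 1, SE 0.18, adjusted p = 0.0046). Of the cholesterol synthesis genes 1 rose and 18 were not called (18 rose adjusted over the list alone, median 0.75, camera adjusted p = 7.2e-20, and adjusted p = 0.048 with an estimated correlation, 0.093 with the block as well). With the block 12 rose. In that list Sqle stood at 98.3 and 161 CPM (0.72, adjusted p = 0.052) and Pmvk at 42.7 and 89.8 CPM (1.07, adjusted p = 0.054), and both were called with the block. Without single libraries the changed STAT3 targets numbered 4 to 12 and the cholesterol genes 0 to 10.

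Few immune genes were called with IL-10 alone in WT. Of the maturation genes 2 of 20 rose (5 adjusted over the list alone, 8 with the block, median 0.58, camera adjusted p = 3.8e-05, adjusted p = 0.49 with an estimated correlation). One was Cd274 (115 ± 47.5 to 341 ± 185 CPM, log2 1.56, adjusted p = 0.022), not called without WT1 PBS (0.14), WT2 PBS (0.11) or WT3 IL-10 (0.2). The other was Pdcd1lg2, the gene of PD-L2 (21.7 to 82.5 CPM, 1.92, adjusted p = 0.019), not called without WT1 PBS (0.1), WT2 PBS (0.05) or WT3 IL-10 (0.14). MHC class II presentation had 1 rise among 14 (3 adjusted over the list alone, 3 with the block, median 0.3, 4e-04, adjusted p = 0.23 with an estimated correlation). MHC class I had 1 among 20 (4 adjusted over the list alone, 4 with the block, median 0.27, 0.00011, adjusted p = 0.5 with an estimated correlation). Without single libraries the class II count was as low as 0, and the class I count 0 to 2. No NF-kB target rose over all genes (1 adjusted over the list alone, 4 with the block, median 0.44, 2.7e-05, adjusted p = 0.49 with an estimated correlation, 2 without WT3 PBS). Of 22 inflammatory genes 2 rose (3 adjusted over the list alone, median 0.43, 0.023, adjusted p = 0.57 with an estimated correlation, 1 without WT1 PBS, WT2 PBS or WT3 IL-10). Without WT3 IL-10 the inflammatory median was -0.16. No interferon-stimulated gene was called, over all genes or adjusted over the list alone, but the list had a median of -0.79 (camera adjusted p = 6.7e-07, adjusted p = 0.57 with an estimated correlation). The WT3 PBS library, highest in Isg15 with PBS, moved it, and without it the median was 0.14. Of the interferon-gamma-associated genes 1 rose (5 adjusted over the list alone, 4 with the block, median 0.18, 0.0044, adjusted p = 0.57 with an estimated correlation, 5 without WT3 PBS, median -0.17 without WT3 IL-10). Il12b stood at 180 ± 130 CPM with PBS and 149 ± 105 CPM with IL-10 (log2 -0.27, adjusted p = 0.92) and Cxcl10 at 14.8 ± 20.4 and 4.73 ± 5.07 CPM (-1.66, adjusted p = 0.54). Cd40 stood at 75.1 and 164 CPM (1.12, adjusted p = 0.29, 1.21, adjusted p = 0.028 with the block).

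The remaining lists had few or no calls with IL-10 in WT. Among cDC1 identity genes 0 of 20 were called (1 up adjusted over the list alone, median -0.19, camera adjusted p = 0.11), but 2 rose and 3 fell with the block, where the list passed camera (adjusted p = 0.032, 0.4 with an estimated correlation as well). Among those 3 was Tlr3, the receptor of double-stranded RNA (-1.02, adjusted p = 0.0071 with the block). Of stress and handling genes 1 fell (1 adjusted over the list alone, 2 changed with the block, 2 without WT3 PBS, median -0.03, camera adjusted p = 1). No cell cycle gene (camera adjusted p = 0.18) and neither interferon gene was called. No marker of cDC2s (median 0.01, mean -0.35, 1), pDCs (median 0.58, 0.53), monocytes and macrophages (median -0.22, mean 0.47, 0.67), neutrophils (median -1.03, mean 0.08, 1), mast cells and basophils (median 0.28, mean -0.31, 0.74), lymphocytes (median -0.6, 0.085) or erythroid cells was called. Those counts were also 0 adjusted over the list alone. With the block 4 monocyte and macrophage markers and 1 pDC marker changed, and the lymphocyte markers passed camera (adjusted p = 0.043, 0.26 with an estimated correlation as well).

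In KO cDC1s IL-10 alone changed 3 genes, all up. Socs3 rose from 2.38 ± 0.401 to 25.7 ± 14.2 CPM (log2 fold change 3.43, SE 0.55, adjusted p = 0.026, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Dram1 from 2.01 ± 0.635 to 12.9 ± 5.42 CPM (2.68, SE 0.38, adjusted p = 0.0091). Rap1gap, a GTPase-activating protein named here after its values were seen, rose from 0.312 ± 0.261 to 3.03 ± 1.21 CPM (3.26, SE 0.54, adjusted p = 0.026). All 3 are among the 143 genes that rose in WT. Unadjusted, 171 genes had a p under 0.05, and DESeq2 called 11. Bcl3 stood at 43.2 and 73.2 CPM (0.76, adjusted p = 1) and Ier3 at 9.71 and 28.1 CPM (1.53, adjusted p = 0.98, 1.46, adjusted p = 0.042 with the block). With the block 6 genes were called, and Socs3 was not (3.38, adjusted p = 0.061). Socs3 was also lost without the filter (adjusted p = 0.15), with only these groups in the fit (0.51) and without KO1 PBS (0.41), KO2 PBS (0.2), KO3 PBS (0.46), KO2 IL-10 (0.19) or KO3 IL-10 (0.11). Dram1 was lost with only these groups in the fit (0.51) and without KO1 PBS (0.16), KO3 PBS (0.17) or KO2 IL-10 (0.053). The number of genes was 0 (Rap1gap lost too) without KO1 PBS, KO3 PBS or KO2 IL-10, 1 without KO3 IL-10, and 5 without KO1 IL-10. Of the STAT3 target genes 1 rose (2 adjusted over the list alone, median 0.43, camera adjusted p = 3.4e-07, adjusted p = 0.37 with an estimated correlation, 0.0038 with the block as well). By camera glycolysis was also higher (0 called, median 0.27, 3e-10, adjusted p = 0.14 with an estimated correlation). So were cholesterol synthesis (0 called, 0.23, 1.4e-06, adjusted p = 0.52 with an estimated correlation), maturation (0 called, 0.22, 0.0013, 0.79), interferon-gamma-associated genes (0 called, 1 adjusted over the list alone, 0.12, 0.017, 0.81) and MHC class I (0 called, 0.11, 0.031, 0.91). No interferon-stimulated gene was called (median -0.07, 0.59).

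The genotypes' responses to IL-10 alone were compared directly. No gene passed the test of the difference (edgeR's quasi-likelihood test, 248 at an unadjusted p under 0.05, DESeq2 0, 1 with the block, 1 without WT2 IL-10). By camera the effect was lower in KO for STAT3 target genes (median -0.89, adjusted p = 3.5e-12, adjusted p = 0.087 with an estimated correlation). It was lower for glycolysis (-0.39, 3.8e-10, adjusted p = 0.087 with an estimated correlation) and cholesterol synthesis (-0.52, 2.5e-14, adjusted p = 0.13 with an estimated correlation). The interferon-stimulated genes had a difference above 0 (0.68, 2.8e-06, adjusted p = 0.7 with an estimated correlation), with a median of -0.25 without WT3 PBS. NF-kB targets (-0.34, 0.00031), MHC class II (-0.2, 0.0032), MHC class I (-0.15, 0.0043) and maturation (-0.29, 0.018) were lower too and the 3 lymphocyte markers higher (0.85, 0.023), none with an estimated correlation (adjusted p = 0.31 for the class II and lymphocyte lists, 0.7 for the others). No member of these 9 lists was called, over all genes or adjusted over the list alone.

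Under IL-10, KO cells differed from WT cells in 12 genes, 4 higher and 8 lower (846 at an unadjusted p under 0.05, DESeq2 104). Lower in KO was Jak3, a kinase of cytokine receptors named here after its values were seen (101 ± 3.6 CPM in WT, 47.4 ± 4.69 in KO, log2 fold change -1.1, SE 0.16, adjusted p = 0.0072, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Also lower were Myd88, the adaptor of Toll-like receptors (188 to 76.3 CPM, -1.30, adjusted p = 0.021), and the lymphocyte regulator Btla (266 to 118 CPM, -1.17, adjusted p = 0.048). So were Flot1 (-1.39, adjusted p = 0.048), the transcription factor gene Pou2f2 (-1.39, adjusted p = 0.045), Bin2 (-1.27, adjusted p = 0.045) and Dram1 (-1.82, adjusted p = 0.048). Egr2 was higher (1.69 to 6.28 CPM, 1.89, adjusted p = 0.049). Socs3 (111 to 25.7 CPM, -2.12, adjusted p = 0.12) and Bcl3 (177 to 73.2 CPM, -1.27, adjusted p = 0.11) were not called. The STAT3 target genes were lower as a list (0 called over all genes, 12 lower adjusted over the list alone, median -1.10, camera adjusted p = 1.2e-16, and adjusted p = 0.038 with an estimated correlation, 0.057 with the block as well). So was glycolysis (0 called, 9 lower adjusted over the list alone, -0.44, 1.9e-12, and adjusted p = 0.038 with an estimated correlation, 0.068 with the block as well). With the block each list had 1 gene lower. Also lower by camera were cholesterol synthesis (median -0.41, 7.6e-11), MHC class I (-0.27, 3.4e-06), interferon-gamma-associated genes (-0.64, 7.6e-06), maturation (-0.5, 0.00016), the cell cycle (-0.26, 0.00026), MHC class II (-0.28, 0.00026), NF-kB targets (-0.25, 0.007) and the inflammatory list (-0.4, 0.014). The 3 lymphocyte markers were higher (0.74, 0.024). None of these 9 was kept with an estimated correlation (adjusted p = 0.16 to 0.54), and none had a call over all genes, though 4 of them had 1 or 2 with the block. Adjusted over the list alone, 7 interferon-gamma-associated genes and 1 each of the maturation, MHC class II and inflammatory lists were lower, and 1 lymphocyte marker was higher. The number of genes was 0 (all 12 calls lost) without WT1 IL-10, KO1 IL-10 or KO2 IL-10, 1 without WT3 IL-10, 3 without KO3 IL-10, 62 without WT2 IL-10, and 0 with only these groups in the fit. Without WT2 IL-10, 4 STAT3 target genes and 2 glycolysis genes passed over all genes.

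IL-10 added to poly I:C lowered cytokine genes that poly I:C had raised in WT cDC1s, the third question being whether IL-10 restrains the response. Il12a fell from 86.4 ± 20.4 to 2.77 ± 1.89 CPM (SD, n = 3, log2 fold change -4.97, SE 0.47, adjusted p = 3.4e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Il12b fell from 10500 ± 1890 to 1310 ± 896 CPM (-3.00, SE 0.53, adjusted p = 0.00036). Tnf fell from 1400 ± 121 to 336 ± 163 CPM (-2.05, adjusted p = 0.0027) and Ccl3 from 325 ± 16.2 to 29.7 ± 7.58 CPM (-3.45, adjusted p = 4.1e-05). Cxcl10 fell from 1130 ± 171 to 83.6 ± 73.9 CPM (-3.76, SE 0.93, adjusted p = 0.0072) and Ifnb1 from 5.58 ± 1.05 to 0.336 ± 0.432 CPM (-4.03, SE 0.74, adjusted p = 0.0016). Further falls were those of Tnfsf15 (128 ± 23.6 to 4.31 ± 3.12 CPM, -4.89), a ligand of the TNF family, Tnfaip8l3 (23.7 to 0.932 CPM, -4.66) and Ch25h, which makes the antiviral oxysterol 25-hydroxycholesterol (370 ± 63.6 to 14.8 ± 17.5 CPM, -4.65, adjusted p = 0.00054). Rises were led by Slamf1, a co-receptor of lymphocytes and dendritic cells (0.537 to 65.6 ± 27.2 CPM, 6.99, SE 0.98, adjusted p = 5.5e-05), and Muc1, a mucin (0.836 to 83.4 ± 59.9 CPM, 6.70, adjusted p = 0.00018). Next were the metallothionein gene Mt2 (1.4 to 101 ± 67.2 CPM, 6.24, adjusted p = 0.00046) and Plet1 (0.61 to 17.2 ± 10.5 CPM, 4.90, adjusted p = 0.0022). They were followed by Elovl6, an enzyme that lengthens fatty acids (0.901 to 22.3 ± 12.2 CPM, 4.65, adjusted p = 2.4e-06), and Bzw2 (5.79 to 134 ± 62.4 CPM, 4.53, adjusted p = 4.9e-05). Il6 fell from 356 ± 23.7 to 144 ± 52.3 CPM (-1.31, adjusted p = 0.043), a call lost without the filter (0.12) and without WT1 poly I:C (0.085), WT2 poly I:C (0.091), WT3 poly I:C (0.073), WT1 both (0.14) or WT3 both (0.16). In all 3092 genes changed, 1645 up and 1447 down, 1588 by 2-fold or more (850 up, 738 down), and 1866 without WT3 both. Higher calls were 53.2 % of the total with TMM and 79.2 % scaled to total counts only (3157 up, 829 down).

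**Figure D3:**
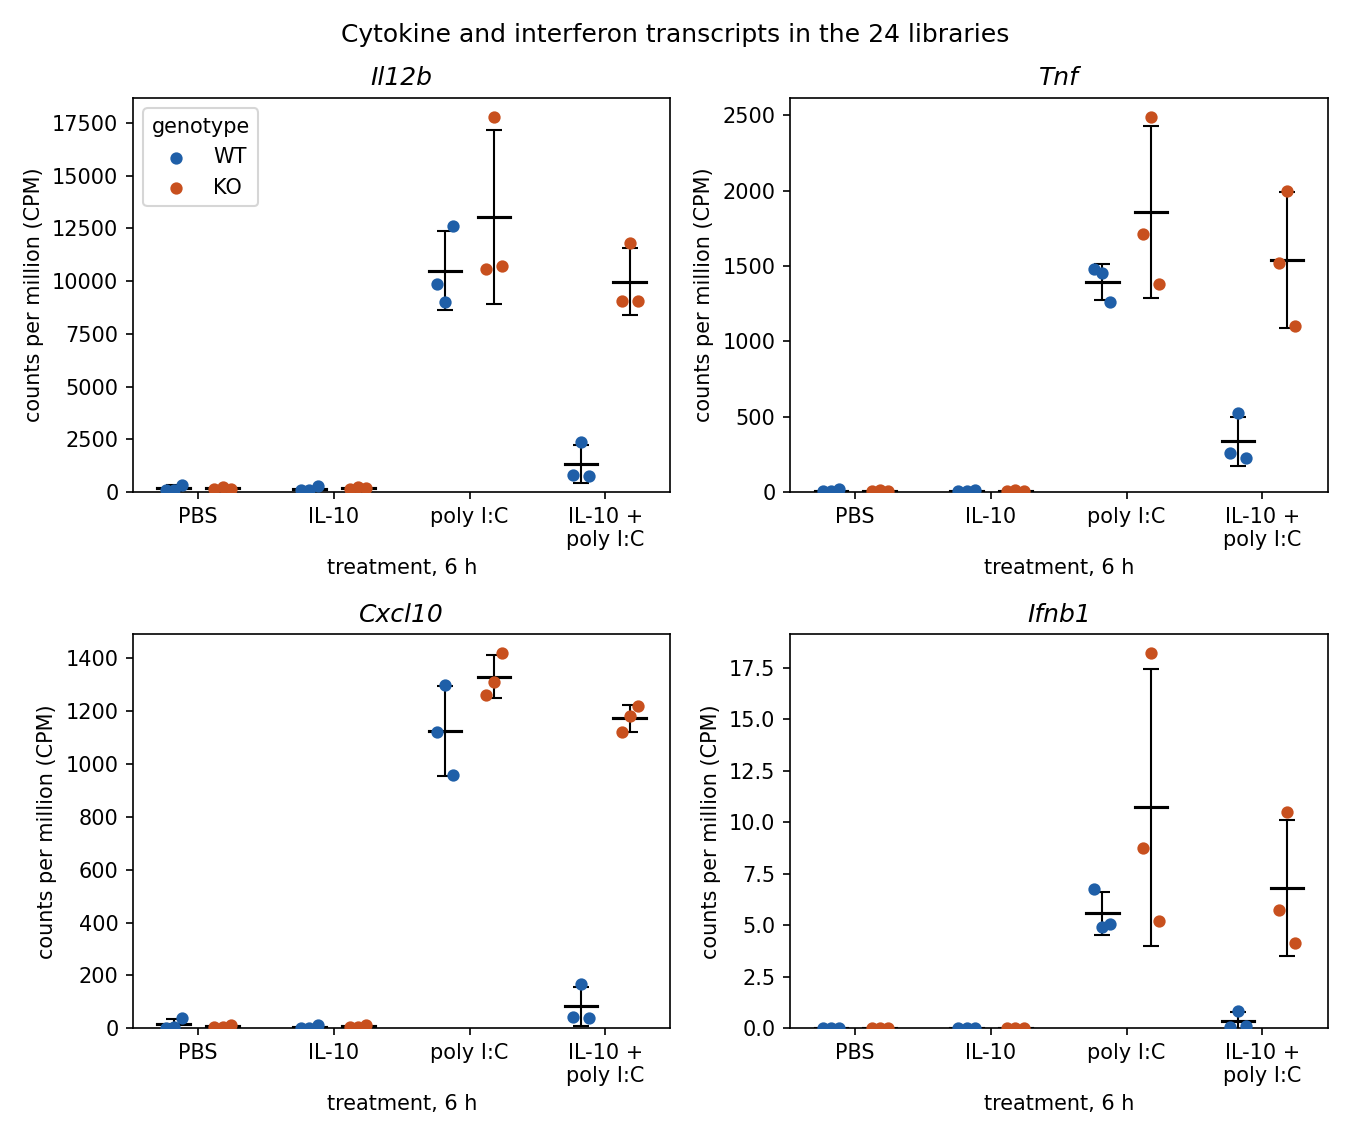
Il12b, Tnf, Cxcl10 and Ifnb1 in CPM per library against treatment for 6 h, WT in blue and KO in orange, with bars for mean ± SD of 3 libraries. With both stimuli, mean Il12b is 1310 CPM in WT and 9950 CPM in KO, and mean Cxcl10 83.6 CPM in WT and 1180 CPM in KO.

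More inflammatory genes fell than rose, and more STAT3 targets rose than fell, when IL-10 was added in WT. Of 22 inflammatory cytokines and chemokines 8 fell and 1 rose (10 and 2 adjusted over the list alone, median -1.18, camera adjusted p = 8.9e-05, adjusted p = 0.54 with an estimated correlation). Of the STAT3 target genes 7 rose and 1 fell (8 and 2 adjusted over the list alone, median 0.47, 0.014, adjusted p = 0.54 with an estimated correlation). Socs3 rose from 170 ± 44.1 to 865 ± 176 CPM (log2 2.35, SE 0.50, adjusted p = 0.0023). Bcl3 rose from 206 to 659 ± 125 CPM (1.68), Sbno2 from 326 to 996 ± 204 CPM (1.61) and Nfil3, a transcription factor, from 18 to 107 ± 49.8 CPM (2.57). Of the interferon-stimulated genes 6 of 40 fell (1 adjusted over the list alone, median -0.83, 7.2e-06, adjusted p = 0.54 with an estimated correlation), and 29 with only these groups in the fit. Trim25, a ubiquitin ligase of RNA sensing, fell from 1020 to 519 CPM (-0.98, adjusted p = 0.0016). Mx1 fell from 2910 to 831 CPM (-1.81, adjusted p = 0.021), lost without WT1 poly I:C (0.053), WT1 both (0.076) or WT3 both (0.1) and without the filter (0.064). Isg15 stood at 1930 and 1650 CPM (-0.23, adjusted p = 0.86), Ifit1 at 1900 and 502 CPM (-1.92, adjusted p = 0.18) and Irf7 at 2890 and 1440 CPM (-1, adjusted p = 0.32). Of the interferon-gamma-associated genes 4 of 20 fell (3 adjusted over the list alone, median -0.65, 0.0076, adjusted p = 0.54 with an estimated correlation), among them Cxcl11 (28.2 to 2.88 CPM). Of the 2 interferon genes Ifnb1 alone fell (1 adjusted over the list alone). Without single libraries the changed genes numbered as few as 1 for interferon-stimulated genes, 5 for inflammatory genes and 5 for STAT3 targets.

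Of the called identity genes most fell, and all called glycolysis and cholesterol synthesis genes rose, on adding IL-10 in WT. Of the cDC1 identity genes 9 fell and 3 rose (10 and 3 adjusted over the list alone, median -0.63, camera adjusted p = 0.015, adjusted p = 0.54 with an estimated correlation). Xcr1, the chemokine receptor that marks cDC1s, fell from 384 ± 42.1 to 122 ± 67.9 CPM (log2 -1.65, adjusted p = 0.00031), Cadm1 from 144 to 60.5 CPM (-1.25) and Tlr3 from 14.6 to 2.67 CPM (-2.44). Batf3, a transcription factor that cDC1s need, rose from 29.3 to 95.6 CPM (1.71). Glycolysis had 7 rises among 16 (7 adjusted over the list alone, median 0.3, 0.014, adjusted p = 0.54 with an estimated correlation), with Tpi1 up from 88.1 to 183 CPM. Cholesterol synthesis had 6 among 19 (9 adjusted over the list alone, median 0.49, 0.0016, adjusted p = 0.54 with an estimated correlation), with Mvd up from 30.7 to 78.9 CPM. Scaled to total counts only, identity genes had 4 falls and 3 rises (median -0.36) and cholesterol synthesis had 15 rises. NF-kB targets had 2 rises and 4 falls (2 and 4 adjusted over the list alone, median -0.09, 0.39, 4 rises and 1 fall scaled to total counts only). Maturation had 2 and 3 (2 and 4, median -0.28, mean 0.08, 0.33), MHC class I had 1 and 1 (1 and 0, median -0.2, 0.28) and MHC class II had 2 and 1 (2 and 1, median -0.25, mean 0.11, 0.52). Cd40 (2270 and 1840 CPM, -0.3, adjusted p = 0.66) and Cd274 (1430 and 1380 CPM, -0.05, adjusted p = 0.94) did not pass. Cell cycle had 5 rises (7 up and 1 down adjusted over the list alone, median 0.47, 0.12), and 1 stress gene fell, Atf3 (379 to 102 CPM, 1 adjusted over the list alone, median -0.19, 0.56). With the block the changed members numbered 10 for maturation, 5 for MHC class I, 7 for MHC class II, 8 for cell cycle and 5 for stress. Without single libraries the changed genes numbered as few as 5 for cDC1 identity, 3 for glycolysis, 3 for cholesterol synthesis, 2 for NF-kB targets, 0 for MHC class I and 1 for the cell cycle, and as many as 8 for maturation and 3 for stress.

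The IL-10 genes of resting and stimulated WT cells overlapped. Of the 143 genes that rose with IL-10 alone, 101 (70.6 %) also rose when it was added to poly I:C, against 17.5 for independent lists, and of the 5 that fell 3 also fell. The comparisons share no library, though the same 3 cultures supplied both. Of 2879 genes that poly I:C raised by 2-fold or more in KO, 697 (24.2 %) fell and 151 (5.24 %) rose on adding IL-10 in WT. Of 3831 genes that it lowered by 2-fold or more in KO, 156 (4.07 %) fell and 751 (19.6 %) rose. Of the 6735 other genes, 594 (8.82 %) fell and 743 (11 %) rose.

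In KO cDC1s no gene fell past the threshold when IL-10 was added to poly I:C. Il12b stood at 13000 ± 4170 CPM with poly I:C and 9950 ± 1560 CPM with both (SD, n = 3, log2 fold change -0.39, adjusted p = 1, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Tnf stood at 1860 ± 570 and 1540 ± 447 CPM (-0.27, adjusted p = 1) and Cxcl10 at 1330 and 1180 ± 49.8 CPM (-0.18, adjusted p = 1). Ifnb1 stood at 10.7 and 6.82 ± 3.32 CPM (-0.65, adjusted p = 1) and Il6 at 458 and 471 CPM (0.04, adjusted p = 1). In all 64 genes rose, 58 of them by 2-fold or more, and 0 fell (768 at an unadjusted p under 0.05). DESeq2 called 119 up and 4 down, and the fit without the filter 65 and 2. Ptpn1, a phosphatase that restrains cytokine receptor signalling, rose from 17.3 ± 6.32 to 147 ± 60.5 CPM (3.08, SE 0.33, adjusted p = 0.00012). Ptger2, a prostaglandin E2 receptor, rose from 0.411 ± 0.288 to 3.86 ± 1.4 CPM (3.17, SE 0.51, adjusted p = 0.0029) and Gadd45g from 4.01 ± 1.32 to 33.8 ± 27 CPM (3.07, SE 0.48, adjusted p = 0.0029). Bzw2 rose from 4.16 to 57.5 ± 49.2 CPM (3.82, adjusted p = 0.0048), lost without KO1 poly I:C (0.053). Muc1 rose from 0.171 to 25.2 ± 18.1 CPM (7.24, adjusted p = 0.011), lost without KO1 poly I:C (0.069), KO2 poly I:C (0.074), KO3 poly I:C (0.092) or KO2 both (0.054). All 64 also rose in WT, against 7.83 for independent lists. Socs3 stood at 161 ± 44.1 and 432 ± 70.6 CPM (1.42, adjusted p = 0.45). Nfil3 was called with the block alone (1.52, adjusted p = 0.087, 1.47, adjusted p = 0.0013 with the block). The number of genes was 102 with the block (1 down) and 14 with only these groups in the fit (where Ptger2, Gadd45g and Bzw2 were lost, adjusted p = 0.11, 0.12 and 0.19). It was 30 without KO1 poly I:C, 31 without KO2 poly I:C, 36 without KO3 poly I:C and 23 without KO2 both.

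The STAT3 target genes were the one list past camera when IL-10 was added in KO (0 called over all genes, 5 rose adjusted over the list alone, 2 with the block, median 0.58, adjusted p = 3.4e-07, adjusted p = 0.7 with an estimated correlation, 0.047 with the block as well, 1 called without KO1 both). The inflammatory list had 0 calls (0 adjusted over the list alone, median -0.09, camera adjusted p = 0.91) and the interferon-stimulated genes 0 (0 adjusted over the list alone, median -0.05, 0.86). No cDC1 identity gene was called (0 adjusted over the list alone, median -0.13, 0.32, 0.044 with the block, 0.97 with the block and an estimated correlation). Of the remaining lists, maturation and MHC class II had 1 rise each (2 each with the block, and 2 for maturation without KO1 both). Both were lost without KO2 poly I:C, KO3 poly I:C or KO2 both, that of maturation also without KO1 poly I:C and that of MHC class II without KO3 both.

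The effect of IL-10 on the poly I:C response differed between genotypes. The difference, KO effect minus WT effect, was 4.83 for Il12a (log2, SE 0.59, adjusted p = 0.0013, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and 4.10 for Tnfaip8l3 (SE 0.61, adjusted p = 0.0021). It was 4.31 for Tnfsf15 (SE 0.69, adjusted p = 0.0037) and 3.12 for Ccl3 (SE 0.63, adjusted p = 0.013). It was below 0 for Pik3r2, a regulatory subunit of PI3-kinase (-2.28, SE 0.40, adjusted p = 0.0045). So it was for Chst12, a sulfotransferase (-2.16, SE 0.43, adjusted p = 0.01, 0.058 with only these groups in the fit), and Agfg2 (-1.93, SE 0.39, adjusted p = 0.011, 0.079 with only these groups in the fit). Il12b (2.61, SE 0.70, adjusted p = 0.051), Ifnb1 (3.38, SE 0.94, adjusted p = 0.078), Cxcl10 (3.58, SE 1.22, adjusted p = 0.14), Tnf (1.78, SE 0.62, adjusted p = 0.14), Socs3 (-0.93, adjusted p = 0.54) and Isg15 (0.53, adjusted p = 0.85) did not pass. With the culture as a block Il12b (2.61, adjusted p = 0.017) and Ifnb1 (3.64, adjusted p = 0.022) passed, as did Tlr3 (1.95, adjusted p = 0.0027) and Cadm1 (1, adjusted p = 0.0092). In all 364 genes differed, 232 above 0 and 132 below, 283 by 2-fold or more (182 above, 101 below), and 735 with the block. Calls above 0 were 63.7 % of the total with TMM and 26.7 % scaled to total counts only (133 above, 365 below). The number of genes was 103 with only these groups in the fit, and without single libraries from 115 (WT1 both) to 834 (WT2 both).

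**Figure D4:**
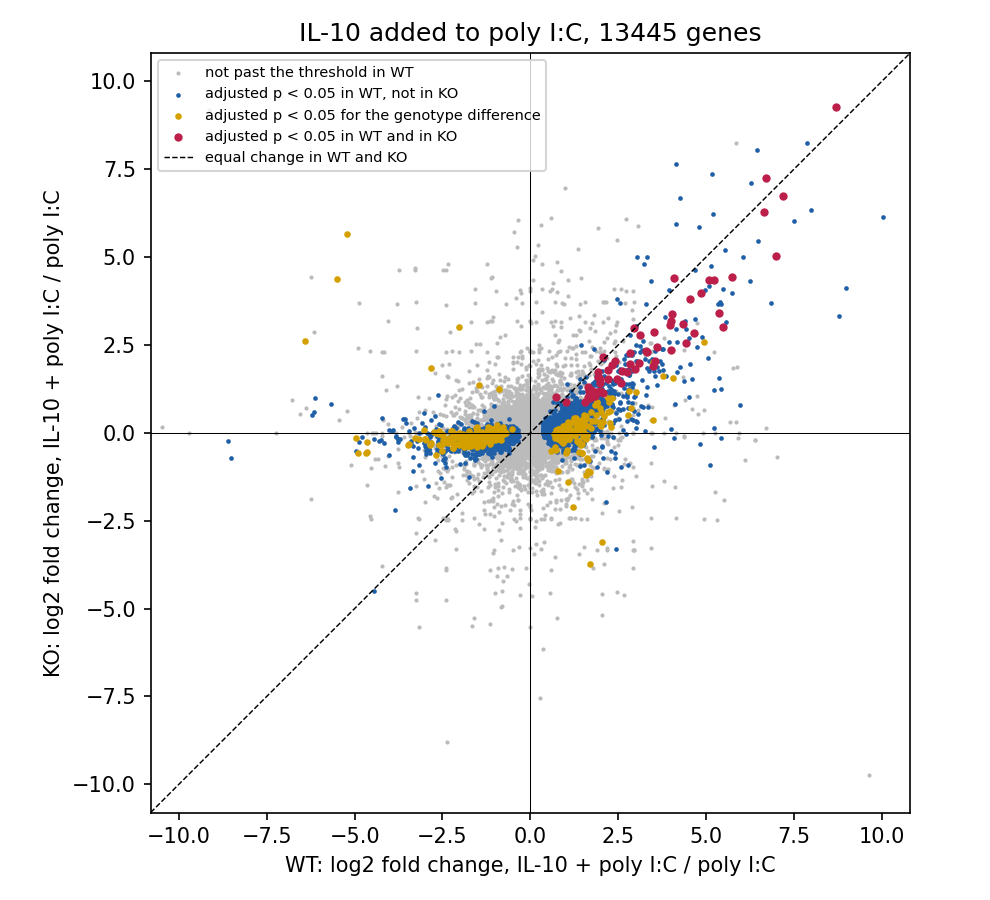
Log2 fold change of IL-10 added to poly I:C in WT (horizontal axis) against KO (vertical axis) for 13445 genes, with the dashed line at equal change and colours for genes called in WT alone, in both genotypes, or in the test of the difference. The 364 genes past the test of the difference are in gold, and the 64 genes called in KO lie on the rising side in WT.

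As lists, inflammatory and interferon genes were lowered less by IL-10 in KO than in WT by camera. The difference had a median of 0.89 for the inflammatory list (2 genes above 0 and 20 not called, 3 adjusted over the list alone, camera adjusted p = 7.2e-06). It was 0.79 for the interferon-stimulated genes (0 called, 0 adjusted over the list alone, 7.9e-06) and 0.89 for the interferon-gamma-associated genes (1 above 0, 4 adjusted over the list alone, 0.00018). With only these groups in the fit 4, 6 and 3 genes of these lists were above 0. It was below 0 for cholesterol synthesis (1 below, 1 adjusted over the list alone, median -0.48, 0.00018) and the cell cycle (0 called, 0 adjusted over the list alone, median -0.48, 0.036). For these 5 lists it was not kept with an estimated correlation (adjusted p = 0.63 for each with an estimated correlation). The STAT3 target genes did not pass (0 called, 1 below with the block, median -0.18, 0.43). Maturation (0.078, 0.045 with the block), cDC1 identity (0.057, 0.019 with the block) and glycolysis (0.057, 0.045 with the block) passed with the block alone, but not with an estimated correlation as well (adjusted p = 0.61 each). With the block the called genes numbered 1 for interferon-stimulated, 2 for interferon-gamma-associated, 3 for maturation and 4 for cDC1 identity genes. The interferon-gamma-associated call, Cxcl11, and the cholesterol call, Mvd, were each lost without any 1 of 9 libraries. The called inflammatory genes numbered 4 without WT2 both, the interferon-gamma-associated genes 3 without WT2 both, and maturation and cDC1 identity genes 2 and 3 without WT2 both and 1 and 2 without KO2 both.

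Under both stimuli several inflammatory transcripts stood higher in KO cells than in WT cells. Il12a stood at 2.77 ± 1.89 CPM in WT and 127 ± 43.2 CPM in KO (SD, n = 3, log2 fold change 5.52, SE 0.48, adjusted p = 3e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Il12b at 1310 ± 896 and 9950 ± 1560 CPM (2.92, SE 0.53, adjusted p = 0.00062). Tnf stood at 336 and 1540 CPM (2.19, SE 0.46, adjusted p = 0.0021) and Ccl3 at 29.7 and 363 CPM (3.61, adjusted p = 4.3e-05). Cxcl10 stood at 83.6 ± 73.9 and 1180 ± 49.8 CPM (3.81, SE 0.94, adjusted p = 0.0079) and Ifnb1 at 0.336 and 6.82 ± 3.32 CPM (4.32, SE 0.74, adjusted p = 0.0013). Ch25h (14.8 and 469 CPM, 4.99), Tnfaip8l3 (4.38), Tnfsf15 (4.36) and Tnfsf8 (4.27) were also higher in KO. Lower in KO were Vwa1 (-5.65, adjusted p = 3.6e-05), Bin2 (44.1 and 6.72 CPM, -2.71, SE 0.25, adjusted p = 6.5e-07), Gpr146 (-2.48) and Plxnb2, a semaphorin receptor (146 and 28.3 CPM, -2.37, adjusted p = 2.9e-06). Plet1 was lower too (-3.41, adjusted p = 0.012), except without WT1 both (0.06). In all 2630 genes differed, 1341 higher and 1289 lower in KO, 1245 by 2-fold or more (651 higher, 594 lower). The number was 1148 with only these groups in the fit, 1580 without WT1 both and 1607 without WT3 both. Higher calls were 51 % of the total with TMM and 20.6 % scaled to total counts only (754 higher, 2900 lower).

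Of the inflammatory list 11 were higher and 1 lower in KO under both stimuli (13 and 2 adjusted over the list alone, median 1.45, camera adjusted p = 1.2e-05). Interferon-stimulated genes had 4 higher (1 adjusted over the list alone, 16 with only these groups in the fit, 7 with the block or DESeq2, median 0.77, 1.2e-05) and interferon-gamma-associated genes 5 (5 adjusted over the list alone, 8 with only these groups, median 0.87, 0.00049). MHC class I presentation had 4 higher and 1 lower (5 and 1 adjusted over the list alone, median 0.41, 0.034), and cholesterol synthesis 4 lower (4 adjusted over the list alone, median -0.33, 0.012). None of these 5 calls was kept with an estimated correlation (adjusted p = 0.7 for each with an estimated correlation). Scaled to total counts only, MHC class I had 1 higher and 2 lower (median 0.1) and cholesterol synthesis 11 lower. With only these groups in the fit they had 0 and 1 called. Socs1, another inhibitor of cytokine signalling, stood at 41.3 CPM in WT and 117 CPM in KO (log2 1.51, adjusted p = 0.001), Cxcl11 at 2.88 and 27 CPM (3.23), Cd80 at 42.3 and 100 CPM (1.25) and Tlr3 at 2.67 and 14.5 CPM (2.44). The STAT3 targets Bcl3 (659 and 257 CPM, -1.36, adjusted p = 0.0027) and Sbno2 (996 and 456 CPM, -1.13, adjusted p = 0.0022) were lower in KO. Of that list 4 were lower and 1 was higher (4 and 1 adjusted over the list alone, median -0.37, camera adjusted p = 0.18). Socs3 was not called (865 and 432 CPM, -1, adjusted p = 0.15). Of the cDC1 identity genes 6 were higher and 3 lower (7 and 3 adjusted over the list alone, median 0.26, 0.18). Irf8 was among the higher ones (2170 and 4590 CPM, 1.08, adjusted p = 0.0026). Isg15 (1650 and 2460 CPM, 0.58, adjusted p = 0.63), Ifit1 (502 and 1770 CPM, 1.82, adjusted p = 0.21) and Irf7 (1440 and 2870 CPM, 0.99, adjusted p = 0.33) were not called with the spread of all 8 groups. Without single libraries the numbers were as few as 1 for interferon-stimulated genes, 6 for inflammatory genes, 0 for MHC class I, 2 for STAT3 targets and 2 for cholesterol synthesis.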

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

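The test for cells with intact Stat3 among the KO cells was chosen after its result was seen. The values given first are here because the test of the difference found the effect of adding IL-10 to poly I:C to differ between WT and KO, in 364 genes. Of the named genes the difference (KO effect minus WT effect, log2) was above 0 for Il12a (4.83), Ch25h (4.38), Tnfsf15 (4.31), Tnfaip8l3 (4.1), Tnfsf8 (4.08), Cxcl11 (3.14), Ccl3 (3.12) and Atf3 (1.72). It was below 0 for Gpr146 (-2.49), Pik3r2 (-2.28), Chst12 (-2.16), Scd2 (-2.11), Rfxank (-1.98), Agfg2 (-1.93) and Mvd (-1.34). Some calls were lost when a single library was left out, with these adjusted p: Ch25h without any 1 of 6 libraries (0.053 to 0.088), Tnfsf8 of 5 (0.053 to 0.072), Cxcl11 of 9 (0.058 to 0.098), Gpr146 of 7 (0.068 to 0.091), Scd2 of 6 (0.054 to 0.088) and Mvd of 9 (0.052 to 0.12). Rfxank was lost without KO3 poly I:C (0.061), and Atf3 without WT1 (0.06) or WT3 (0.058) both.

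A response to IL-10 remained in KO cultures given poly I:C. Over 421 genes that rose in WT, the change in KO1, KO2 and KO3 was 13.5, 31.5 and 17.1 % of the WT change (mean 20.7 %, SD 9.54), and over 493 genes that fell it was 14.7, 34.4 and 13.6 % (mean 20.9 %, SD 11.7). Whether culture KO2 alone accounts for it stays open. KO1 and KO3 had a mean share of 15.3 % over the rising genes, under 2 times the SD. The 64 calls became 27, 3 and 15 without KO1, KO2 or KO3 in turn. Cells with intact Stat3 among the KO cells would give rising and falling genes alike shares. The shares differed by -0.161 percentage points (SD 3.33). Partial signalling in every KO cell, untested, could give this too, so both stay open.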

How the results depend on the processing

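Scaling to total counts only and leaving out whole cultures were chosen after seeing the data. The counts of changed genes for poly I:C in WT and KO stayed within 1.5 times under every alternative run. For the others the cause of a move was not tested, except that fits without a library or with only the groups compared have fewer samples to estimate the spread. Of the 13 counts, 13 stayed within 1.5 times under total counts only, 12 with DESeq2 size factors, 11 without the filter, and 6 each with DESeq2, only the compared groups and the block. DESeq2 called 371 genes for IL-10 in WT, 11 for IL-10 in KO, 123 for IL-10 added to poly I:C in KO and 702 for the genotype difference in that response. For KO against WT it called 1 gene under PBS, 104 under IL-10 and 7 under poly I:C. DESeq2 size factors gave 1 gene for KO against WT under poly I:C. Without the filter there were 4 there and 25 under IL-10. With only the compared groups the counts were 10 for IL-10 in WT, 0 for IL-10 in KO, 14 for IL-10 added to poly I:C in KO, 1, 0 and 1148 for KO against WT under PBS, IL-10 and both stimuli, and 103 for the genotype difference. With the replicate block they were 532, 6 and 102 for the same 3 treatment comparisons, 735 for the genotype difference in the response to IL-10 added to poly I:C and 1 for that to IL-10. Across genotypes the culture numbers did not pair the libraries, with correlations of -0.18 to 0.54 in 12 pairs, 8 of them over 0.1. The block gave 70 genes for KO against WT under IL-10 and 3 under poly I:C.

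With each library, or all libraries of a culture, left out in turn, the counts were 15 to 230 for IL-10 in WT (lowest without WT1), 1205 to 3305 for IL-10 added to poly I:C in WT (lowest without WT1), 0 to 5 for IL-10 in KO and 3 to 90 for IL-10 added to poly I:C in KO (lowest without KO2). For KO against WT they were 0 to 62 under IL-10, 0 to 1 under poly I:C and 1338 to 2848 under both stimuli (lowest without WT1). For the genotype differences they were 0 to 1 for IL-10, 0 to 1 for poly I:C and 6 to 834 for IL-10 added to poly I:C (lowest without WT1). Without the WT1 culture, 15 genes were called for IL-10 in WT, and without WT3 61, of which 55 were among the 148. Without KO1, KO2 or KO3 there were 0 for IL-10 in KO.

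Some medians changed sign when a library was left out. Those of the interferon-stimulated genes ranged from -1.41 to 0.14 for IL-10 in WT, from -1.41 to 0.03 for KO against WT under PBS, from -0.25 to 1.33 for the genotype difference in the response to IL-10 and from -0.08 to 1.43 for that to poly I:C. Those of the interferon-gamma-associated genes ranged from -0.17 to 0.93, from -1.33 to 0.13 and, for poly I:C, from -0.07 to 1.4. Library WT3 PBS, with the highest Isg15 among PBS libraries, set the end of each of these ranges that changed sign, or the whole of culture WT3 did, except for the -0.17, which came without WT3 IL-10. Inflammatory medians ranged from -0.16 to 1.02 for IL-10 in WT and from -0.83 to 0.03 for KO against WT under IL-10 (sign changed without WT3 IL-10). Maturation ranged from -0.03 to 0.49 for IL-10 in KO (without KO2 IL-10) and from -0.62 to 0.09 for the genotype difference (without WT3 IL-10), and cholesterol synthesis from -0.02 to 0.28 for KO against WT under PBS (without KO2 PBS).

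Under total counts only, 6646 of the 7186 genes called both ways kept their direction with poly I:C in WT, and 6710 of 7369 in KO. Calls of named genes that changed sign were Cd74 (-0.07 in WT, -0.01 in KO), Hk2 (-0.11 in WT) and H2-Eb1 (-0.24 in KO) with poly I:C. The medians of glycolysis (-0.11 in WT, to 0 in KO), cholesterol synthesis (-0.12, -0.27) and MHC class II presentation (-0.71, -0.88) did so too. Of 247 list tests, 165 kept their side of the threshold with an estimated correlation and 82 lost it. Of 1214 results for named genes, 373 were called. Summed over alternatives, opposite signs with no call in either fit numbered 547, repeats included. Of 100 simulated 2-fold differences between genotypes, 25 were called in the response to IL-10 and 69 under poly I:C (4-fold, 90 and 94). So simulated 2-fold differences in that response were mostly missed.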

Other observations

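The tests for KO cells under a WT label, for a share of them and for male cells were chosen after their results were seen. Further genes moved when IL-10 was added to poly I:C in WT (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ifi30, a thiol reductase that unfolds antigens in lysosomes, rose from 148 to 976 ± 568 CPM (SD, n = 3, log2 fold change 2.72, adjusted p = 0.0068), and March1, a ubiquitin ligase for MHC class II, from 2.43 to 7.64 CPM (1.65, adjusted p = 2.3e-05). Fcgr3, an Fc receptor gene, rose from 0.703 to 4.83 CPM (2.8, adjusted p = 0.0083). Il7r, a receptor of lymphocytes, fell from 10.3 to 2.61 CPM (-1.98, adjusted p = 0.0062).

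Culture WT2 responded less to IL-10 than WT1 and WT3. Its median change over genes chosen in the other cultures was 62.6 % of theirs for 75 genes rising with IL-10 alone, 59.4 % for 516 genes rising when it was added to poly I:C, and 56.2 % for 630 genes falling. KO cells alone under its label are argued against, since Stat3 of WT2 lay above the highest KO library by more than the KO SD in 4 of 4 treatments. Its Stat3 was still the lowest of the WT cultures in each treatment, so less Stat3 in its cells stays open, untested. A share of cells from the KO cultures is argued against, since Xist in WT2 was at most 0.43 % of the lowest KO library of the treatment. Lower depth is argued against, since the share stayed at or below 64.7 % after thinning all libraries to one total. So is a smaller response to poly I:C, since its rise was 105 % of the mean of the others (log2 1.84, 1.98 in WT1 and 1.52 in WT3), and other stimuli were not tested. The cause stays open, and no other biological explanation was tested.

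Xist, the RNA that silences one X chromosome in female cells (ENSMUSG00000086503.3, GRCm38 chromosome X, 103460366 to 103483254, minus strand), stood at 0.548 to 1.91 CPM in the 4 libraries of WT2 and at 287 to 1020 CPM in the 20 others. Male cells are argued against, since 3 Y-linked genes summed to at most 0.33 CPM in a WT2 library. The presence of only one X chromosome stays open: 4 genes that escape silencing (Kdm6a, Kdm5c, Ddx3x and Eif2s3x) had a median log2 ratio of -0.43 in WT2 to the mean of the other cultures, against 0.03 to 0.31 in the others, which is consistent with it. The labels used here name no sex of the mice.

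The 6 libraries of each comparison can be split into groups of 3 in 10 ways, too few for a share under 0.05. In the comparisons between genotypes the 6 cultures were regrouped instead. Beside each real count stands the highest of the other splits. For IL-10 in WT the counts were 148 and 29, for poly I:C in WT 8965 and 0, for IL-10 added to poly I:C in WT 3092 and 1, for IL-10 in KO 3 and 0, for poly I:C in KO 9074 and 0, and for IL-10 added to poly I:C in KO 64 and 33. For KO against WT they were 12 and 1 under IL-10, and 2630 and 105 under both stimuli. For the genotype difference in the response to IL-10 added to poly I:C they were 364 and 0. In each of these 9 comparisons 1 of the 10 splits, the real one, gave as many genes. For KO against WT under PBS (0 and 1) and poly I:C (0 and 1), and for the genotype differences in the response to IL-10 (0 and 0) and poly I:C (0 and 0), all 10 splits gave as many. Of the 4 splits in each treatment comparison that part all 3 pairs, the highest other count was 1 in WT with IL-10 added to poly I:C and 0 in the other 5 comparisons.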
